A study of Mus musculus with 8 samples.

How the data were processed

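The samples were 8 preparations of NK cells, stained for NK1.1 and CD3 and sorted by flow cytometry from spleens of C57BL/6 mice 8 to 12 weeks old, per the labels. Purified cells received mouse IL-15 at 100 ng/mL or vehicle for 24 h, per the labels' protocols. The descriptions number resting replicates 1 and 2 with 0 and activated replicates 1 and 2 with 24, and those of replicates 3 and 4 date each resting sample 1 day before its activated sample. It is therefore open whether vehicle-treated cells were cultured as long as activated cells, and time in culture may be part of every difference. The gate is named by its stains only. The sources used here do not state whether replicates came from separate mice or cultures, and p-values then measure only the spread between these samples, which may be technical. Groups and replicate numbers were taken from the sample titles. The labels say that 100 ng of total RNA was dephosphorylated and labelled with Cy3 at its 3′ end.

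The deposited scanner files came from Agilent Feature Extraction 9.5.3.1, per the file headers, and hold background-subtracted spot intensity in 1 colour with no normalization between arrays. The series table, also intensity, was identical to the processed signal of the scanner files (largest difference 0). All 8 arrays were scanned together on 1 slide. The 2 series of sample names lay in the 2 rows of the slide. Each array lists 12553 spots, 11520 of them for miRNAs, and 0 spots were saturated. The array names 566 mouse miRNAs and 10 miRNAs of a mouse herpesvirus. Names are those of the array design, and 7 of them join several miRNAs. The array design was annotated on mm6 and the gene table used here on GRCm38.p6, so no coordinates are given.

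Control spots and spots marked as outliers were left out, and spots of a probe were averaged. A probe was well above background on an array if at least 0.5 of its spots were. Only 22.4% of probe values were, so each array was divided by the 75th percentile of the 208 probes detected on all 8 arrays. Values were then floored at 0.0512, the highest over the arrays of the lowest scaled signal above background (log2 of -4.29), and log2 was taken. Of 1352 tested values, 458 lay at this floor, and such values have no order. A miRNA was represented by its probe with the highest mean over all arrays. It was tested when that probe was well above background on at least 4 arrays, which left 169 miRNAs and set 397 aside. At the floor on all 8 arrays were 24 of the tested miRNAs. limma's prior had 0.480 degrees of freedom with them and 1.76 without them, where 26 miRNAs were called (9 higher, 17 lower). Where a group lay wholly at the floor, the fold is a bound.

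Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg, threshold 0.05), with no block in the main fit. Lists of miRNAs were tested with fry, which asks whether members move on balance one way. They were also tested with camera at an estimated correlation between members, which asks whether members move more than the other tested miRNAs. A list called by fry and lost by camera may therefore move without moving more than the rest. Numbers of detected miRNAs were compared by an exact permutation test over 70 splits, which cannot go under 0.0286. Fixed before the data were examined were 16 lists, the tests, most alternatives and the rule for named miRNAs. That rule took up to 12 miRNAs with the largest difference in each direction among those past the threshold, miR-223, miR-155, miR-21, miR-150, miR-181a and miR-181b in any case, and up to 4 tested members of each list with the largest absolute difference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

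Resting and activated arrays with the same replicate number were alike, so the numbers were taken as pairs in some fits. Deviations from the group means of resting and activated arrays with the same number correlated across miRNAs at 0.575, 0.737, 0.595 and 0.716, and 7 of 8 arrays correlated best with the array of their own number. With deviations taken within each name series the correlations were lower, 0.516 for replicates 1 and 2 and 0.276 for replicates 3 and 4, so the difference between series makes up part of the values above. That difference also favours matches within a series, so the 7 of 8 matches are not separate pieces of evidence. Each series gives a single such correlation, since its 2 arrays of a group deviate by equal and opposite amounts. The pairing comes from the numbers in the titles and this check. Arrays with the same number also lay side by side in 1 row of the slide, resting in columns 1 or 3 and activated in columns 2 or 4. Likeness by number can therefore not be told apart from place on the slide. The replicate block was planned as an alternative. Tried besides were other scalings, another background correction (normexp, offset 50), the deposited series table, the per-gene signal of the scanner, other rules for probes, filter, floor and variance, a block for the name series, each array left out, and probes of any species.

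The tests were checked on values simulated from the means and spreads of the 169 miRNAs of the activated against resting comparison, with 42 changed miRNAs in each of 20 simulations. Without a block, 16.4% of changes of 0.5, 55.7% of changes of 1 and 74.6% of changes of 1.5 on the log2 scale were called, and 1.44% of calls were false. With the replicate block these shares were 47.1%, 82.9% and 95.4%, and 3.81% of calls were false. The simulated values held a replicate effect for each miRNA, so the gain from the block was built in. Noise was drawn independently between miRNAs, and changes were placed only on miRNAs with a mean more than 1 above the floor. The shares may therefore not carry over to the measured values, of which 458 of 1352 lay at the floor.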

Results

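MicroRNA levels were compared between resting and interleukin-15 (IL-15) activated natural killer (NK) cells sorted from the spleens of C57BL/6 mice. NK cells are innate lymphocytes that kill infected and transformed cells, and IL-15 is a cytokine that drives their survival, growth and activation. Total RNA was hybridised to a custom 1-colour array of mouse miRNA probes. There were 8 arrays, 4 of vehicle-treated (resting) and 4 of activated cells, and they lay on 1 slide. Between 111 and 207 of the 566 mouse miRNA names on the array were well above background per array. Tests are two-sided unless called one-sided, and the number of arrays limits their precision.

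The first question was how many miRNAs could be measured in each state. Resting cells had 164.2 ± 41.0 detected miRNAs per array (SD, n = 4) and activated cells had 159.5 ± 25.7 (SD, n = 4). The difference of -4.75 was smaller than the spread between arrays (exact permutation test, p = 0.83). In resting cells 111 miRNAs were detected on all 4 arrays, in activated cells 123, and 101 of these were shared. These counts are capped by the arrays with the fewest detected, resting array 3 with 111 and activated array 1 with 125. On at least 3 of 4 arrays, 155 were detected in resting and 154 in activated cells, with 145 shared. A single miRNA, miR-210, a hypoxia-inducible miRNA named here after its values were seen, was detected on all 4 activated arrays and on 1 resting array. It lay at the measurement floor on all 4 resting arrays, and its log2 difference of 2.33 did not pass the test (limma, adjusted p = 0.117).

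The second question was which miRNAs changed on activation. Of 169 tested miRNAs, 18 passed the threshold, 7 higher and 11 lower in activated cells (limma, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group). Among those that rose, miR-155, a miRNA induced in activated lymphocytes, was 2.78-fold higher, a log2 difference of 1.47 ± 0.20 (SE; adjusted p = 0.00748 by limma). miR-221 was 2.13-fold higher (1.09 ± 0.17, adjusted p = 0.0114 by limma). miR-20a and miR-20b, members of the growth-associated miR-17/miR-92 family of clusters, were 1.96-fold and 1.83-fold higher, and miR-18a of the same family was 2.14-fold higher. miR-7a rose 2.15-fold and miR-98, a let-7 relative, 1.38-fold, but each was at the measurement floor on 3 of the 4 resting arrays, so their sizes are uncertain. All 7 were higher in activated cells for every one of the 4 replicate numbers. With normexp background miR-155, miR-221, miR-20a and miR-20b kept their calls, and miR-7a (0.22), miR-18a (0.60) and miR-98 (0) did not (limma, adjusted p = 0.276, 0.162 and 1).

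**Figure D1:**
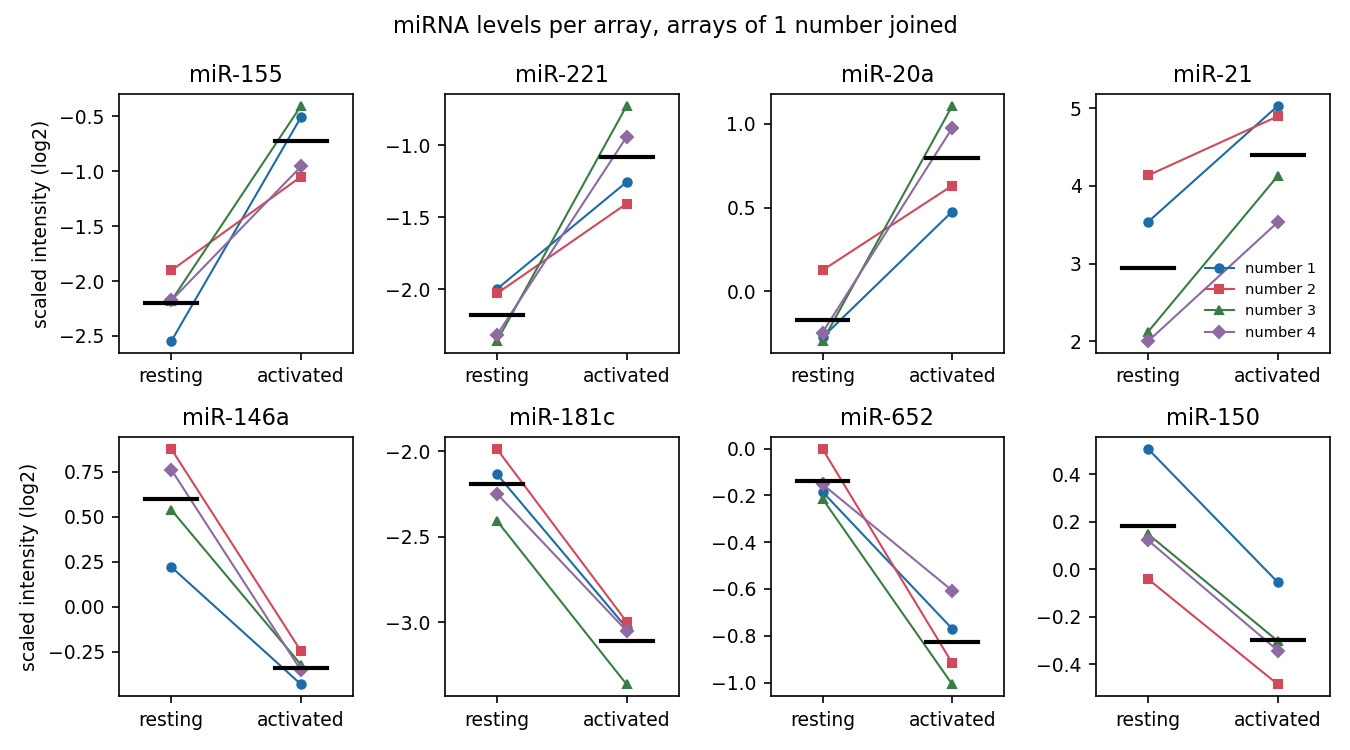
Scaled intensity (log2, vertical axis) of 8 miRNAs on the 4 resting and 4 activated arrays; lines join the arrays that share a replicate number and black bars are group means. miR-155, miR-221 and miR-20a rose and miR-146a, miR-181c and miR-652 fell without overlap between groups; miR-21 and miR-150 did not pass in the main setting (limma, adjusted p = 0.182 and 0.0811).

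Among the miRNAs that fell, miR-146a, a feedback inhibitor of innate immune signalling, was 1.92-fold lower, a log2 difference of -0.94 ± 0.14 (SE; adjusted p = 0.0109 by limma). miR-181c was 1.89-fold lower (-0.92 ± 0.12, adjusted p = 0.0070 by limma), and its relative miR-181a was lower by at least 1.44-fold, since all 4 activated arrays lay at the floor. That bound holds for the main scaling and floor only. Over the other settings the log2 difference of miR-181a ran from -1.03 to -0.11. miR-483 was 1.96-fold lower, miR-466c-5p 1.79-fold, miR-652 1.61-fold and miR-30e 1.61-fold lower. miR-140*, miR-185, miR-149 and miR-30a were lower, with log2 differences of -0.63, -0.62, -0.59 and -0.54, and these 4 were the calls whose sign turned under some scaling. With the percentile taken over all probes miR-185, miR-149 and miR-30a turned, with quantile normalization miR-185 and miR-30a, and without scaling miR-140*, miR-185 and miR-149. With the percentile over all probes only miR-181a of the 11 kept its call, and miR-146a (-0.32), miR-181c (-0.29), miR-483 (-0.38), miR-466c-5p (-0.21), miR-652 (-0.064) and miR-30e (-0.062) shrank and did not pass; that scaling moved every miRNA above the floor upward alike, which removes falls and keeps rises whatever their cause. After quantile normalization miR-146a, miR-181c, miR-652, miR-30e and miR-140* kept their calls. All 7 higher calls were kept under both scalings. With normexp background miR-146a, miR-181c, miR-652 and miR-140* kept their calls, and the other 7 lower ones did not. All 11 were lower in activated cells for every replicate number. Of 27 further probes compared, 22 differed by at least 0.1 in the same direction as the probe used, and 0 differed by that much the other way. The other 5 lay within 0.1 of 0, 3 of them at the floor, where nothing was measured. For miR-181a no further probe was compared, and for miR-7a, miR-149 and miR-466c-5p not all were.

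The numbers of calls depended on the pairing of the arrays and on the scaling. With the replicate number as a block, limma called 42 miRNAs, 12 higher and 30 lower, and 15 of the 18 were among them; miR-18a, miR-466c-5p and miR-149 were not (adjusted p = 0.0819, 0.0656 and 0.0656). The share of higher calls was 38.9% (7 of 18), against 93.8% (30 of 32) with the percentile over all probes and 75% (15 of 20) after quantile normalization, and no scaling gave 0 calls (limma; 22 at an unadjusted p under 0.05). The median log2 difference of the tested miRNAs was -0.08 in the main setting. For the 71 miRNAs above the floor throughout, log2 differences lay 0.62 higher with the percentile over all probes, 0.64 higher without scaling and a median of 0.12 higher after quantile normalization, so every fold change is relative to the scaling. Activated array 1 and resting array 3 had the widest spread of negative control spots. Without both, 6 miRNAs were called, 0 higher and 6 lower (limma; 11 higher and 20 lower at an unadjusted p under 0.05). Without resting array 4 there were 10 calls and without resting array 2 there were 29.

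**Figure D2:**
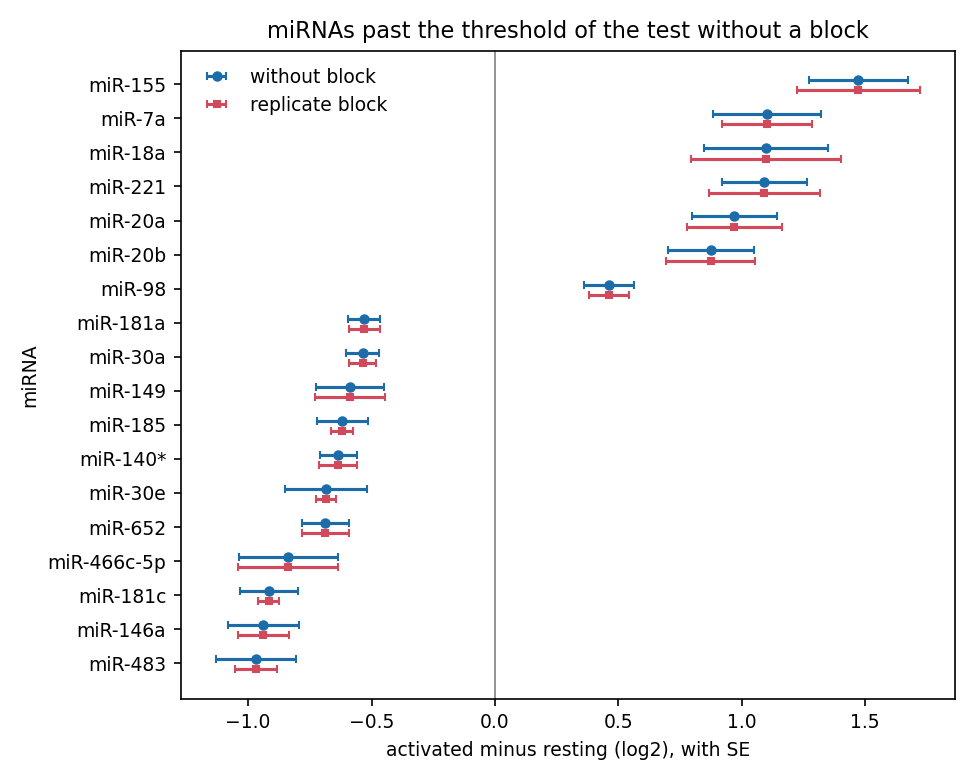
Log2 difference (activated minus resting, horizontal axis) with its SE for the 18 called miRNAs, estimated by limma without a block (blue) and with the replicate block (red). Values run from 1.47 for miR-155 to -0.97 for miR-483.

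The third question was whether groups of miRNAs chosen before the data were examined moved together. Of 10 lists with at least 3 tested members, 3 were called (fry in limma, which asks whether the members shift on balance in 1 direction, adjusted over lists). The 5 tested miRNAs of the lymphocyte activation-induced list rose on balance, with a median log2 difference of 1.09 (adjusted p = 0.0188 by fry in limma). The call was lost by camera, which sets members against the other tested miRNAs (adjusted p = 0.179 with an estimated correlation of -0.019). miR-155 and miR-221 rose and miR-146a fell, and both counts were the same when adjusted over the list alone (2 higher, 1 lower). miR-21 differed by 1.45 (2.73-fold) and miR-212 by 0.26 without passing. miR-21 had a large spread between arrays, with log2 levels of 2.95 ± 1.05 in resting and 4.40 ± 0.70 in activated cells (SD, n = 4), and passed with the replicate block (limma, adjusted p = 0.0308). Without that block miR-21 also passed after quantile normalization (1.87) and with the name series block (limma, adjusted p = 0.0330 and 0.0103). The remaining 7 members were not tested, and 6 of the 12 were above background on no array.

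Members of the miR-17/miR-92 and paralogous clusters also rose on balance, with 11 of 13 tested members above 0 and a median log2 difference of 0.52 (adjusted p = 0.0434 by fry in limma). This call was not kept by camera (adjusted p = 0.179 with an estimated correlation of 0.31). miR-18a, miR-20a and miR-20b passed the test, also when adjusted over the list alone. miR-17, with a difference of 0.84 and all 4 resting arrays at the floor, and miR-106b, at -0.46, did not pass. The miR-181 family, which tunes lymphocyte receptor signalling, fell, with a median of -0.53 over 3 tested members (adjusted p = 0.00122 by fry in limma). This call was also lost by camera (adjusted p = 0.179 with an estimated correlation). The estimated correlation was -0.033, so correlation between members does not account for that loss. miR-181a and miR-181c fell and miR-181d differed by -0.09, but miR-181d was called higher with the percentile over all probes (0.53) and after quantile normalization (0.45; limma, adjusted p = 0.0245 and 0.0450). miR-181b was above background on 2 resting arrays and 1 activated array and was not tested. With the replicate block, the activation-induced and the miR-17/miR-92 lists were no longer called (adjusted p = 0.106 for both), and the miR-181 list was (adjusted p = 0.00483). The fall of the miR-181 list was not called with the percentile over all probes (adjusted p = 0.977) or after quantile normalization (adjusted p = 0.579). Near-identical relatives such as miR-20a, miR-20b, miR-17 and miR-106a can share probe signal, so their separate values are uncertain.

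**Figure D3:**
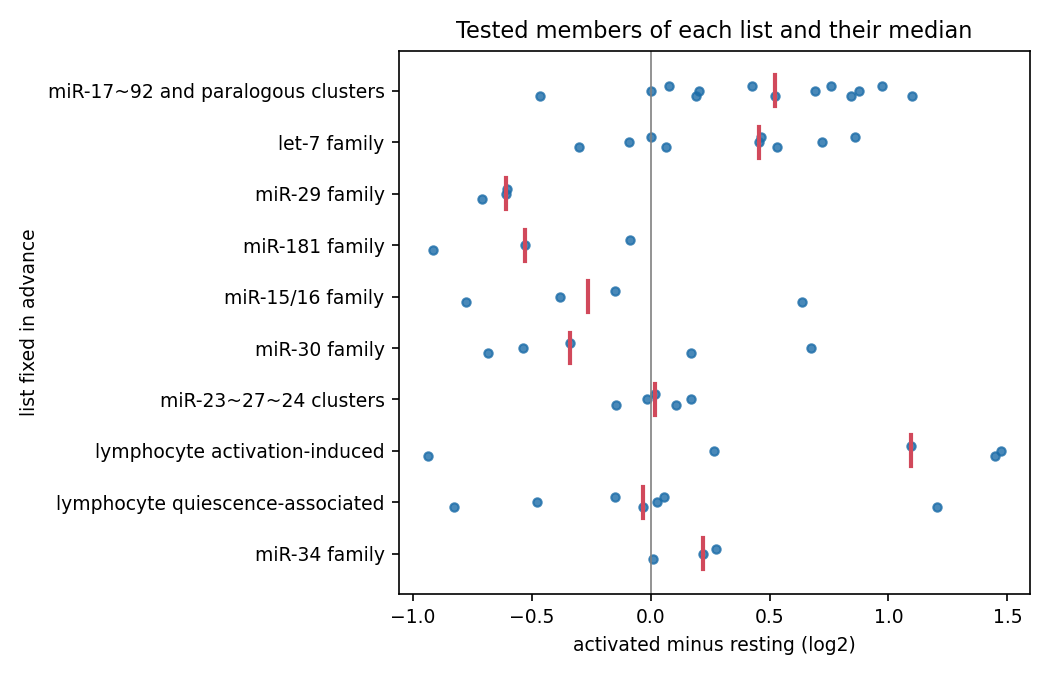
Log2 difference (activated minus resting, horizontal axis) of each tested member (points) of the 10 lists with at least 3 tested members, with the median of each list (red bar). Medians run from -0.61 for the miR-29 family to 1.09 for the activation-induced list; with the percentile over all probes the medians of the miR-29, miR-15/16, miR-30 and quiescence-associated lists were positive.

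The other lists did not pass in the main setting. The 3 members of the miR-29 family had log2 differences of -0.61 (miR-29a), -0.71 (miR-29b) and -0.61 (miR-29c), with an adjusted p = 0.367 for the list, and were called with the replicate block (adjusted p = 0.00483 by fry in limma), where all 3 members passed. The adjusted p = 0.844 with an estimated correlation for this list, whose members correlated at 0.988, and its median was 0.015 with the percentile over all probes and 0.034 without scaling. In the miR-30 family, miR-30a and miR-30e fell, miR-30d differed by -0.34 and miR-30b by 0.68, and the last pair passed in opposite directions with the replicate block (limma, adjusted p = 0.0112 and 0.0313). The list (adjusted p = 0.0751) was called downward with that block (adjusted p = 0.00368 by fry in limma; adjusted p = 0.844 with an estimated correlation). Its median was 0.28 with the percentile over all probes, 0.081 after quantile normalization and 0.30 without scaling. The lymphocyte quiescence-associated list had 4 of 7 members below 0 and a median of -0.03 (adjusted p = 0.697; 0.00483 with the replicate block; adjusted p = 0.912 with an estimated correlation). miR-150, a miRNA of mature resting lymphocytes, differed by -0.48 ± 0.14 (SE) and passed with the block (limma, adjusted p = 0.0811 without and 0.00974 with it). It was 0.14 higher in activated cells with the percentile over all probes and 0.16 higher without scaling. miR-26b differed by 1.20 and miR-101a by -0.83, both passing with the block (limma, adjusted p = 0.0131 and 0.0126). Without a block miR-26b also passed with the percentile over all probes (limma, adjusted p = 0.0478). Within the let-7 family, of 9 tested members, miR-98 rose, let-7f differed by 0.86, let-7a by 0.53 and let-7g by 0.72, the last passing with the replicate block (limma, adjusted p = 0.0313; list adjusted p = 0.0831); adjusted over the list alone, 3 members were higher. The list was called upward with the percentile over all probes (median 0.92, adjusted p = 0.0268 by fry in limma) and after quantile normalization (0.62, adjusted p = 0.0207), but not with an estimated correlation (camera, adjusted p = 0.703 and 0.322 under these scalings). The miR-15/16 family (miR-15a -0.78, miR-15b 0.64, miR-16 -0.38, miR-195 -0.15), the miR-232724 clusters (miR-23a 0.17, miR-23b 0.10, miR-24 -0.15, miR-27b -0.02) and the miR-34 family (miR-34c 0.27, miR-34b-5p 0.22, miR-34a 0.01) had list adjusted p = 0.488, 0.879 and 0.232. The miR-34 list was called upward under the same 2 scalings (0.81 and 0.49, adjusted p = 0.00315 and 0.0289 by fry in limma), and the miR-232724 list with the percentile over all probes (0.64, adjusted p = 0.0471). With an estimated correlation neither was called (camera, adjusted p = 0.434 and 0.322 for miR-34, 0.703 for miR-232724). With the replicate block miR-15a was lower and miR-15b higher (limma, adjusted p = 0.0213 and 0.0300).

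Markers of other cells were examined because a sorted preparation can hold some. miR-451, a red cell miRNA, was 2.30-fold lower in activated cells (-1.20 ± 0.37, SE), which passed with the replicate block and not without it (limma, adjusted p = 0.0313 and 0.0906). It also passed without a block on normexp background (-0.62, adjusted p = 0.0355 by limma). miR-223, a granulocyte and monocyte miRNA, was lower by at least 1.56-fold, with all 4 activated arrays at the floor, and did not pass (limma, adjusted p = 0.0632 without and 0.0767 with the block). That bound holds for the main scaling and floor only. Over 31 other settings the log2 difference of miR-223 ran from -1.64 to -0.12, and it passed in 6 of them. miR-223 passed with the percentile over all probes (-0.50), with the total gene signal (-1.63) and with a lower floor (-1.64; limma, adjusted p = 0.0473, 0.00406 and 0.00251), so its size depended on the floor and the signal used. miR-486 lay at the floor on all 8 arrays. The other 3 myeloid markers, miR-144, 10 of 12 stromal and endothelial markers and 13 of 15 other tissue-restricted miRNAs were above background on no array. The 10 count miR-199b and miR-199a-3p apart, though they share an array name. Of the epithelial markers only 3 of 7 were above background on no array. miR-200a and miR-10a were above background on 4 resting and 4 activated arrays. miR-200b was so on 3 and 4, but lay at the floor on 7 of the 8. Of the remaining marker lists, miR-214 differed by -0.02, miR-200a by -0.36 and miR-200b by -0.03 without passing, and miR-10a by 0.75, passing with the replicate block and with the name series block (limma, adjusted p = 0.0131 and 0.0424). miR-142-3p and miR-142-5p, expressed in all blood cells, differed by -0.68 and -1.10 and passed with the replicate block (limma, adjusted p = 0.0276 and 0.0112), not without it (adjusted p = 0.590 and 0.193).

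The last question was whether the activation difference varied between the 2 series of sample names, replicates 1 and 2 against replicates 3 and 4. Within the first series 6 miRNAs were called (1 higher, 5 lower) and within the second 33 (15 higher, 18 lower), in a limma fit over all 8 arrays. The difference between the series itself was called for 0 of 169 miRNAs (limma, lowest adjusted p = 0.234; 15 at an unadjusted p under 0.05). miR-155 differed by 1.45 in the first series and by 0.05 more in the second, and miR-146a by -0.89 and -0.99. miR-221 differed by 0.68 and by 0.82 more in the second series, and miR-20a by 0.63 and 1.31. With the name series as a block, limma called 44 miRNAs, 14 higher and 30 lower, and all 18 were among them.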

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

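All tests in this part were chosen after the results were seen.

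A single array lay far from the other 3 in 4 of 87 examined groups of 4 arrays whose values all lay above the floor, where chance gives about 4.35. The 87 groups did not cover all tested miRNAs. miR-20a in resting array 2 was at 0.13 on the log2 scale against -0.30 to -0.25 in the other arrays. miR-185 in resting array 2 was at -2.87 against -3.19 to -3.18. In activated array 3, miR-181c was at -3.36 against -3.05 to -3.00, and miR-140* was at 0.13 against 0.36 to 0.39.

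Probes for small structural RNAs, used on the array as controls and not part of the miRNA comparison, differed between the groups. Of 23 such probes above background on all 8 arrays, 7 were called higher in activated cells in a limma fit with the replicate block (adjusted p under 0.05), each for all 4 numbers. They were 3 probes for m4.5SrRNA, the array name of a short rodent RNA (log2 differences 0.76, 0.65 and 0.58), 2 for U4 (0.48 and 0.34), 1 for U6 (0.66) and 1 for MRP RNA (0.30). Probes of 1 RNA did not all move together. The 4 probes of U6 ranged from -0.43 to 0.66 and those of U4 from -0.29 to 0.48, whereas those of m4.5SrRNA ranged from 0.27 to 0.76 and those of U1 from -0.44 to -0.26. Within m4.5SrRNA, U1, U4, U6 and U32 the difference fell with each higher probe number, and higher-numbered probes were mostly brighter. The MRP RNA probes went the other way (0.22 and 0.30). An effect of the probe may therefore be part of these differences. In the fit with the replicate block 9 probes were called lower in activated cells, among them all 4 of U1. Without the block 0 of the 23 probes passed (limma, lowest adjusted p = 0.655).

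The m4.5SrRNA signal was weighed further. A brightness or scaling factor common to all probes of an array would leave its ratio to U1 unchanged. That log2 ratio was 0.95 higher in activated cells, with every activated above every resting array (SD 0.19 and 0.06, n = 4, exact permutation test, p = 0.0286, the smallest possible, 0.0571 adjusted over 4 RNAs). The ratio cannot test an array effect that differs between probes, and the 4 probes of U6 alone ran from -0.43 to 0.66. The ratio of U6 to U1 was 0.37 higher with the same p. Of the RNAs with at least 3 probes, m4.5SrRNA had the highest mean difference (0.57) and U1 the lowest (-0.38). The p of their ratio is thus that of a pair picked from these values. Without a reference the m4.5SrRNA difference had p = 0.286 (exact permutation test). A rise of all control RNAs would lift the others too, but among the other 4 RNAs with at least 3 probes the highest mean difference was 0.081 against 0.57 for m4.5SrRNA. With RNAs of 2 probes included, the highest of 6 was 0.26, for MRP RNA. A ratio shows unequal change and not which RNA changed. IL-15 itself, time in culture, the 3′ ends of the RNAs and an effect of the probe stay open and may each contribute, since none was tested.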

How the results depend on the processing

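The splits of the samples, the alternatives without both noisy arrays, without miRNAs at the floor on all 8 arrays or with values above the floor on at least 4 arrays, and those joining the replicate block or camera with another scaling or background were chosen after the results were seen; the others were fixed before the data were examined. Counts are from limma and values are log2 differences, medians for lists, whose direction is that of the test unless the median is named.

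In the main setting 18 miRNAs were called (7 higher, 11 lower) and 3 lists. The percentile over all probes gave 32 (30 higher, 2 lower) and 5 lists, and quantile normalization 20 (15 higher, 5 lower) and 4 lists. Without scaling 0 miRNAs (0 higher, 0 lower) and 0 lists were called, with 22 miRNAs at an unadjusted p under 0.05. Of the 18 miRNAs, 15, 16 and 15 kept their direction under these 3 scalings. Normexp background gave 11 (4 higher, 7 lower), of which 8 were among the 18, and 1 list, without the miR-17/miR-92 and activation-induced lists (adjusted p = 0.0553 for both, fry in limma), total gene signal 34 (14 higher, 20 lower), no filter 6 (1 higher, 5 lower), and a lower floor 34 (11 higher, 23 lower). The series table gave the same values. The replicate block gave 42 (12 higher, 30 lower) and 4 lists, the name series block 44 (14 higher, 30 lower) and 6 lists, and array weights 48 (21 higher, 27 lower) and 5 lists. Within name series 1 there were 6 calls (1 higher, 5 lower), and within name series 2 there were 33 (15 higher, 18 lower) and 6 lists.

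Leaving out 1 array gave 10 to 29 calls (2 to 13 higher, 8 to 16 lower) and 1 to 4 lists. The number of calls moved more than 1.5-fold without resting array 4 (10) and without resting array 2 (29). The difference in detected miRNAs per array ran from -22.5 to 9.5, and was positive without resting array 1, activated array 1 or resting array 2. Without both noisy arrays 6 miRNAs (0 higher, 6 lower) and 1 list were called. Values above the floor on at least 4 arrays gave 25 (8 higher, 17 lower), and without miRNAs at the floor on all 8 arrays there were 26 (9 higher, 17 lower). The replicate block gave 39 (38 higher, 1 lower) and 7 lists with the percentile over all probes, 36 (17 higher, 19 lower) with quantile normalization, 0 (0 higher, 0 lower) and 0 lists with no scaling, where 46 miRNAs had an unadjusted p under 0.05, and 24 (6 higher, 18 lower) with normexp background. Camera with an estimated correlation called 0 lists, and its direction for the quiescence-associated list, at -0.034, was upward.

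Among the list calls, the replicate block lost the miR-17/miR-92 and activation-induced lists and added the miR-29, miR-30 and quiescence-associated lists, and it changed no other list call. Joined with the percentile over all probes, it called the miR-30 and quiescence-associated lists upward. The activation difference between name series was called for 1 miRNA after quantile normalization (miR-720, 0.57) and for 2 without scaling (miR-181a, 0.76, and miR-34b-5p, 0.59).

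Directions turned with the percentile over all probes, with or without the replicate block, for the lists of miR-15/16 (0.22), miR-30 (0.28) and quiescence-associated miRNAs (0.59), and the median of the miR-29 list turned to 0.015. They also turned for miR-185 (0.0042), miR-149 (0.036), miR-30a (0.087), miR-150 (0.14), miR-200a (0.16), miR-200b (0.24), miR-139-5p (0.47), miR-16 (0.24), miR-195 (0.19), miR-181d (0.53), miR-24 (0.47), miR-27b (0.61), miR-29a (0.015), miR-29c (0.018) and miR-30d (0.28). Quantile normalization turned the lists of miR-15/16 (0.032) and quiescence-associated miRNAs (0.10), and the median of the miR-30 list turned to 0.081. It also turned miR-185 (0.033), miR-30a (0.081), miR-200b (0.076), miR-139-5p (0.075), miR-195 (0.13), miR-181d (0.45), miR-24 (0.000592) and miR-27b (0.11).

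Without scaling the lists of miR-29 (0.034), miR-15/16 (0.15), miR-30 (0.30) and quiescence-associated miRNAs (0.60) turned. So did miR-140* (0.0066), miR-185 (0.014), miR-149 (0.055), miR-150 (0.16), miR-200b (0.13), miR-139-5p (0.49), miR-16 (0.26), miR-195 (0.032), miR-181d (0.30), miR-24 (0.49), miR-27b (0.62), miR-29a (0.034), miR-29c (0.036) and miR-30d (0.30).

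The remaining turns were of small differences. Normexp background turned the miR-34 list and miR-34c (-0.00365) and miR-34b-5p (-0.012). Total gene signal turned the quiescence-associated list (0.052), miR-200b (0.13) and miR-27b (0.039), and a lower floor turned miR-200b (0.073). The mean over probes turned the miR-23-27-24 list (-0.058) and miR-23b (-0.076). Within name series 1 the miR-23-27-24 list (-0.10), the miR-34 list and miR-34c (-0.038) and miR-34b-5p (-0.22) turned. Within name series 2 miR-181d (0.095), miR-27b (0.069) and the test direction of the miR-15/16 list (median -0.24) turned, and with array weights miR-27b (0.18) did. The median of the lymphocyte quiescence-associated list turned to 0.045 within name series 2 and was also above 0 with array weights. With 1 array left out, miR-27b ran from -0.20 to 0.15, miR-195 from -0.24 to 0.029, miR-181d from -0.19 to 0.017, the miR-23-27-24 list from -0.16 to 0.16 and the quiescence-associated list from -0.15 to 0.057. Without both noisy arrays the miR-23-27-24 list (-0.15) and miR-23b (-0.018) turned.

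Of the 35 splits of the 8 arrays into 4 and 4, 1 gave at least the 18 calls of the real split, which was that split itself, and the highest other count was 15, from the split by name series. For lists 2 of the 35 gave at least 3, the real split and the split by name series (4), a share that does not exclude chance. With the replicate block only 1 of the 8 splits that part all numbers gave as many calls, for miRNAs (42, highest other 0) and for lists (4, highest other 0), and 8 splits are too few for a share under 0.05.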

Other observations

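All tests in this part were chosen after the results were seen, and the miRNAs named here were picked after their values were seen.

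Of the miRNAs outside the lists, 11 passed with the replicate block and not without it, all lower in activated cells. Their calls depended on the scaling. With the block 1 of the 11 passed with the percentile over all probes (miR-466f-3p, -0.75), 6 after quantile normalization and 0 without scaling, and 10, 11 and 10 of them were below 0 under these 3 scalings. The percentile over all probes and no scaling moved miRNAs above the floor upward alike, by 0.62 and 0.64. Signs under those scalings thus follow from the size of each fall and do not show stability. On normexp background with the block 3 of the 11 passed, and miR-671-5p, miR-680, miR-466f-3p, miR-705 and miR-139-3p were among those that did not. miR-671-5p differed by -1.39, miR-680 by -1.27, miR-466f-3p by -1.27, miR-574-5p by -1.08, miR-423-5p by -1.02 and miR-705 by -0.97 (limma with the block, adjusted p = 0.0112, 0.0269, 0.0100, 0.0282, 0.0112 and 0.0313). miR-130b differed by -0.45 and miR-139-3p by -0.68 (adjusted p = 0.0242 and 0.0135).

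The 2 series of sample names differed in level. Of 169 miRNAs, 35 differed between replicates 1 and 2 and replicates 3 and 4, 24 lower and 11 higher in the second series (limma with treatment in the fit). This fit counts all arrays of a series as independent. Each series holds only 2 replicate numbers, whose arrays deviated together, so its p-values may be too small. miR-142-3p was lower by a log2 difference of -1.91, miR-101a by -1.54 and miR-21 by -1.45, while miR-671-5p was higher by 1.52, miR-714 by 1.49 and miR-709 by 1.28. Of 18 splits of each group into 2 and 2, 1 gave as many calls, the real split, and 18 splits are too few for a share under 0.05. Most of these splits also part arrays that share a number. Scaling is argued against, as 26 of the 35 passed in the same direction after quantile normalization. Against noise of activated array 1 and resting array 3 the evidence is weaker. Without them the median ratio of the absolute differences was 1.03 and all 35 kept their direction, but only 19 still passed. The 35 were picked on values that include the arrays kept here, which favours a ratio near 1. Brightness of the probe is argued against for the 22 miRNAs with several measurable probes, whose dimmest and brightest probes parted by a median of 0.038, against a series difference of 0.95. The series cannot be told apart from the row of the slide, since all 8 arrays lay in the row of their series, and probe length and the base composition of the miRNAs were not analysed here; a difference between cell preparations may also remain.

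Lower miR-223 and miR-451 in activated cells may come from RNA of other cells lost in culture. As a test of RNA of other cells lost in culture, 7 marker miRNAs of myeloid cells, red cells and platelets were read, of which 4 were above background on no array, and too few were measured to decide. The sort on NK1.1 and CD3 and the lysis of red cells may have removed such cells, but purity was not measured here. miR-451 was above background on 4 resting and 4 activated arrays, and miR-223 on 4 and 3. A change within NK cells also stays open.

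A hypothesis was that miRNAs encoded side by side change alike because they share a transcript. Of the tested miRNAs, 146 of 169 matched a gene of GRCm38.p6 by name. Over 32 pairs of different families within 10 kb, the mean absolute gap between log2 differences was 0.36, against 0.598 for random pairs (one-sided permutation test with 100000 resamples, p = 0.0141, 0.0282 adjusted over 2 tests). The test counted narrower gaps only, so its p is smaller than a two-sided one would be. A narrower gap is what the hypothesis predicts, although values at the floor narrow some gaps. Many of the pairs lie in the miR-17/miR-92 and paralogous clusters, already seen to rise on balance, and share members such as miR-19b. The test is therefore not separate from that list result. Of the 14 pairs above the floor throughout, 8 moved in the same direction. For 17 pairs of arms of 1 hairpin the gap was 0.486 (one-sided permutation test, p = 0.169), and no likeness was shown.

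Probes for the 10 herpesvirus miRNAs gave signal in 3 cases. The probe for mghv-miR-M1-2 was above background on all 8 arrays (30.5 ± 8.63 intensity units in resting and 47.0 ± 31.2 in activated cells, SD, n = 4), that for mghv-miR-M1-8 on 7 arrays and that for mghv-miR-M1-6 on 3, while 7 names were above background on no array. These signals were weak and were not scaled or floored. The 75th percentile used for scaling ran from 500 to 1762 units per array. Binding of other RNAs to these probes was not tested, so the signals do not show that viral miRNAs were present.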
